A study of Homo sapiens with 4 samples.

How the data were processed

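UMI-4C measures how often one chosen DNA fragment, the bait, is ligated to other fragments of crosslinked chromatin, and its adapter design allows ligation products to be told apart by where the DNA was sheared. Per the labels' protocols, H9 human embryonic stem cells, an established line, were differentiated for 7 days with 1 uM retinoic acid and 5 ng/ml BMP4 towards surface ectoderm. The cells were then fixed in 1% formaldehyde, digested with DpnII and ligated, and bait primers at the TFAP2C locus were used for amplification. The 4 libraries were 2 of wild-type and 2 of p63-null cells. The labels call them duplicates and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

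The deposited values were counts of contacts between pairs of 5 kb bins of chromosome 20, without normalization. Per the submitters' processing notes, HiC-Pro and Bowtie were used and the build was hg19 (GRCh37). Their versions, and whether repeated copies of a ligation product were collapsed before counting, were not given in the sources used here. Without that collapse, a product amplified many times would add many contacts to a single bin, and counting intervals would be too narrow. Floors and the intervals of shares and of pooled ratios cover counting error only. Most replicates differed by more, so the interval of a pooled ratio is no test between genotypes. A 5 kb bin can hold several DpnII fragments, so a bait bin collects the contacts of its neighbouring fragments too. Contacts with other chromosomes were not analysed here.

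Baits were located without using the groups, as bins whose contacts with other bins held over 5% of all contacts between different bins over the 4 libraries. This rule gave 2 bins, and 1 further bin below 5% was added after the data were seen. The bin at 55.20 Mb is called the TFAP2C bait from the labels and from general knowledge of where TFAP2C lies in GRCh37, since no annotation of that build was used here. The gene table used is for GRCh38 and served only for names and the order of genes. For the same reason the planned test of contacts with gene promoters was left out, and bins are described by coordinates alone. TP63, the gene that encodes p63, lies on another chromosome, so the genotype labels were not checked against the data.

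For each bait, contacts within 1 Mb were kept, apart from the bait bin and the bins within 10 kb. Library size was the total of these contacts, and bins with at least 10 contacts over the 4 libraries were tested. The p63-null and wild-type counts were compared with the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over the bins of a bait and a threshold of 0.05. The same test was run on the contacts summed into 10 distance bands, 5 on each side of the bait, adjusted over the 10 bands of that bait. Intervals of band fold changes are 95% intervals from the quasi-likelihood degrees of freedom. Shares of contacts are given as mean ± SD with n = 2 per genotype, with Wilson 95% intervals for single libraries and a two-sided exact permutation test, for which 2 against 2 libraries cannot give a p below 0.33. The ratio of a bin to the distance trend came from a loess (statsmodels 0.14.6, span 0.5) of log2 of the mean scaled contacts plus 0.5 on log2 distance within a genotype. A bin counted as above the trend when its ratio was at least 2 in both replicates.

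Bins were named by a rule set before the data were examined. Where fewer than 5 bins of a bait passed, the 5 with the smallest p were named, together with the 5 highest above the trend in each genotype. The alternatives tried were TMM scaling, DESeq2 1.42.0, a replicate block, leaving out each library, no filter, 20 kb bins, other windows, a distance-trend offset, scaling to all of chromosome 20, a ratio of 1.5 and a loess on each side apart. Those added after the data were seen were the 55.38 Mb bait, a count of distinct partner bins, 15 kb windows around the other baits, sums of the lower side, the sum of the higher side between 100 and 500 kb, the crossed replicate block and 1 interval of 600 kb. In all, 112 bins and 30 bands were tested. The 6 windows around other baits were each tested among the 15 kb windows tiled from that position, 19 to 43 of them, and their adjusted p is over those unless stated.

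The tests were also tried on simulated counts with the depth of these libraries and a single mean dispersion (spread beyond counting error) for each set of bins or bands. For the bands of the TFAP2C bait it was 0.00882. Single bands could vary more: lower 100 to 250 kb held 5.58 and 11.5% in p63-null replicates 1 and 2. The shares of changed bands called may therefore be too high. Over 41 bins of the TFAP2C bait, 7.5% of bins changed 8-fold were called, against 2.5% over 59 bins of the 55.42 Mb bait. Over the 10 bands, 77.5% of those changed 4-fold were called for the TFAP2C bait and 67.5% for the 55.42 Mb bait. For 2-fold changes of bands these shares were 42.5% and 17.5%.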

Results

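UMI-4C contacts of the TFAP2C locus were counted in surface ectoderm cells made from H9 human embryonic stem cells, at day 7 of treatment with retinoic acid and BMP4. TFAP2C encodes a transcription factor of the AP-2 family, and p63 is a transcription factor required for stratified epithelia. There were 2 libraries of wild-type and 2 of p63-null cells. Wild-type replicates 1 and 2 held 30369 and 16744 contacts on chromosome 20, and p63-null replicates 1 and 2 held 29500 and 44199. Pairs within a single 5 kb bin made up 70.8 to 76.8% of these, which left 8402, 4882, 6852 and 12238 contacts between different bins, in the same order of libraries. The 3 bait bins described next took part in 26.5% and 27.9% of the between-bin contacts of the wild-type libraries, but in 16.7% and 13.5% of those of the p63-null libraries, so the deepest library was not the richest in bait contacts.

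A few bins of chromosome 20 (GRCh37) held far more between-bin contacts than any other, though most between-bin contacts involved no bait bin. The bin at 55,420,001 to 55,425,000 held 8.60% of the between-bin contacts and the bin at 55,200,001 to 55,205,000, the TFAP2C bait, held 7.53%. The next bin, at 55,380,001 to 55,385,000, held 3.78% and was added as a further bait after the data were seen. In the gene order of GRCh38, FAM209B precedes TFAP2C and BMP7, which encodes a bone morphogenetic protein, follows it with 0 other coding genes between them. Between 10 kb and 1 Mb, the TFAP2C bait had 464 and 235 contacts in the wild-type libraries and 215 and 330 in the p63-null libraries. The 55.42 Mb bait had 610, 363, 236 and 396, and the 55.38 Mb bait had 213, 124, 90 and 120, in the same order.

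In both genotypes the TFAP2C bait met the higher-coordinate side, towards BMP7, more often than the lower side. The lower side took 18.3% ± 1.23 of the contacts in wild-type and 30.2% ± 5.25 in p63-null cells (SD, n = 2 each). Both p63-null libraries, at 26.5% (Wilson interval 21.1 to 32.8) and 33.9% (29.0 to 39.2), lay above both wild-type libraries, at 19.2% (15.9 to 23.0) and 17.4% (13.1 to 22.8). The exact permutation p was 0.33, the smallest this design allows. This sum over the lower side was chosen after the bands were seen, as was the next sum. The higher side between 100 and 500 kb held 58.3% ± 0.53 of the wild-type and 49.9% ± 7.64 of the p63-null contacts, with the same p. The difference of -8.30 percentage points was -2.90 without p63-null replicate 2 and -13.7 without p63-null replicate 1. The shares of a library are parts of the same total. Falls on the higher side, here and in the bands below, therefore partly restate the rise on the lower side and are no separate evidence.

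Of the 10 distance bands of the TFAP2C bait, the band 250 to 500 kb on the lower side passed the edgeR test. Contacts there rose from 3 and 1 in the wild-type libraries to 7 and 11 in the p63-null libraries. As shares these were 0.54% ± 0.16 and 3.30% ± 0.055 (SD, n = 2 each). The fold change was 2.45 on the log2 scale (SE 0.59, 95% interval 1.06 to 3.84), with an adjusted p of 0.0409 from edgeR's quasi-likelihood test. The ratio of the pooled shares was 5.77 (exact interval 1.90 to 23.4, counting error only). The call rested on 22 contacts. Its adjusted p was 0.0817 over the 20 bands of both planned baits, 0.0664 with the replicate block, 0.189 with DESeq2 and 0.237 with TMM, and between 0.0948 and 0.349 when 1 library was left out.

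The other 9 bands of the TFAP2C bait did not pass. The band 100 to 250 kb on the lower side held 4.18% ± 1.10 of the wild-type and 8.55% ± 4.2 of the p63-null contacts (n = 2 each), a log2 fold change of 1.04 (SE 0.40) with an edgeR adjusted p of 0.124. p63-null replicate 2 held 38 of its p63-null contacts and replicate 1 held 12. Without p63-null replicate 1 this band passed instead, at a log2 fold change of 1.37 and an edgeR adjusted p of 0.00732, and without p63-null replicate 2 its log2 fold change was 0.33 with an adjusted p of 0.723. The nearest band on the higher side, 10 to 50 kb, held 9.20% ± 1.43 and 5.44% ± 0.45 (n = 2 each), a log2 fold change of -0.69 (SE 0.27) with an edgeR adjusted p of 0.124. The band 100 to 250 kb on the higher side held 25.3% ± 4.46 and 18.3% ± 0.24 (n = 2 each), with both p63-null libraries below both wild-type libraries, a log2 fold change of -0.44 (SE 0.26) and an edgeR adjusted p of 0.259. Its difference of -7.04 percentage points was -3.89 without wild-type replicate 2. The bands 250 to 500 kb and 500 to 1000 kb on the higher side held 32.9% ± 4.99 and 9.21% ± 0.22 in wild-type, and 31.6% ± 7.88 and 9.51% ± 1.02 in p63-null cells.

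**Figure D1:**
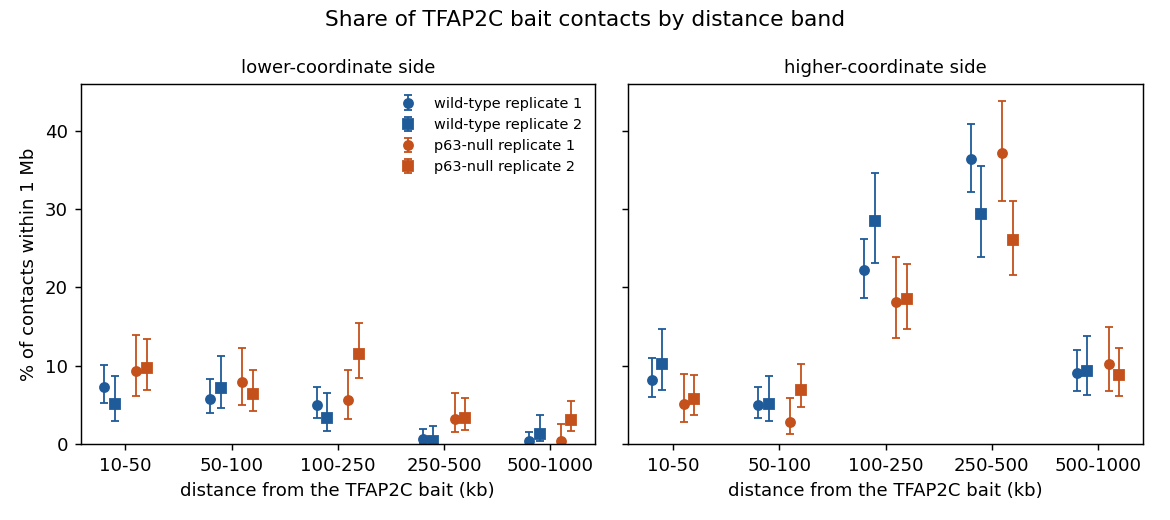
Share of the TFAP2C bait contacts within 1 Mb (percent, vertical axis) in each distance band (kb, horizontal axis), on the lower and higher side. Each point is a library with its Wilson 95% interval. In the band 250 to 500 kb of the lower side the p63-null libraries sit at 3.26 and 3.33% and the wild-type libraries at 0.65 and 0.43%.

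For the 55.42 Mb bait the sides were nearly even. The lower side held 45.2% ± 8.93 of the contacts in wild-type and 45.6% ± 5.16 in p63-null cells (SD, n = 2 each). None of its 10 bands passed the edgeR test, and the smallest adjusted p was 0.90. The band with the smallest p, 500 to 1000 kb on the lower side, held 0.91% ± 0.11 and 0.55% ± 0.42. The 55.38 Mb bait had 38.3% ± 6.32 and 45.4% ± 2.95 of its contacts on the lower side, and none of its 10 bands passed, with a smallest adjusted p of 0.472. With the replicate block, its band 500 to 1000 kb on the lower side (1 and 0 against 5 and 1 contacts) passed, at an edgeR adjusted p of 0.0449. On simulated counts 17.5% of 2-fold changes of a band were called for the 55.42 Mb bait, so changes of that size could be missed; the 55.38 Mb bait was not simulated.

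Single 5 kb bins were compared to ask whether p63 loss changed contacts with particular places. No bin passed in the edgeR test, out of 41 tested for the TFAP2C bait, 59 for the 55.42 Mb bait and 12 for the 55.38 Mb bait. The counts at an unadjusted p under 0.05 were 1, 2 and 0, and DESeq2 also called 0 bins for each bait, with 0, 2 and 0 at an unadjusted p under 0.05. The groups did not overlap in 31.7%, 32.2% and 25% of the bins, where chance gives 33.3%. On simulated counts of this depth few 8-fold changes of single bins were called, so these counts of 0 do not show that contacts were alike.

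None of the bins named next passed the test. The exact intervals given for them cover counting error only, which the spread between replicates mostly exceeded. For the TFAP2C bait, the smallest p belonged to the bin at 55,385,001 to 55,390,000, which lies 185 kb away next to the 55.38 Mb bait. It had 8 and 4 contacts in wild-type and 0 and 0 in p63-null cells, at least 3.12-fold higher in wild-type against a floor of 3 contacts over the p63-null group. That floor leaves out the counting error of the wild-type contacts, and the exact interval of the ratio of p63-null to wild-type reached 0.46 (edgeR adjusted p 0.706). At 55,370,001 to 55,375,000 there were 3 and 13 wild-type and 0 and 1 p63-null contacts. The bins at 55,500,001 to 55,505,000 (1 and 1 against 3 and 5), 55,175,001 to 55,180,000 (1 and 1 against 8 and 3) and 55,120,001 to 55,125,000 (0 and 1 against 9 and 4) had more contacts in the p63-null libraries.

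For the 55.42 Mb bait, the bin at 55,545,001 to 55,550,000 had 14 and 14 contacts in wild-type and 1 and 0 in p63-null cells, a pooled ratio of 0.055 (exact interval 0.0013 to 0.33, edgeR adjusted p 0.429). The bin at 55,570,001 to 55,575,000, 25 kb further on, had 0 and 2 against 12 and 6, a pooled ratio of 13.9 (3.32 to 123.1) and the same adjusted p. Contacts with the bin at 55,235,001 to 55,240,000 were 2 and 8 against 0 and 0, at least 2.17-fold higher in wild-type by the same floor, with an exact interval of the ratio reaching 0.69. The bins at 55,395,001 to 55,400,000 (16 and 5 against 0 and 2) and 55,250,001 to 55,255,000 (2 and 0 against 5 and 5) completed the 5. Without p63-null replicate 1, 1 bin of this bait passed.

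For the 55.38 Mb bait the bins with the smallest p began at 55,430,001, 55,325,001, 55,410,001, 55,200,001 and 55,565,001. The bin at 55,430,001 had 3 and 8 wild-type and 0 and 0 p63-null contacts, at least 2.28-fold higher in wild-type by the same floor, with an exact interval of the ratio reaching 0.64 and an edgeR adjusted p of 0.750. At 55,325,001 there were 1 and 0 wild-type against 1 and 8 p63-null contacts, a pooled ratio of 14.4 (exact interval 2.00 to 633). Those at 55,410,001 were 5 and 4 against 0 and 1, and those at 55,565,001 were 2 and 5 against 2 and 1. The bin at 55,200,001 is the TFAP2C bait itself, with 3 and 8 against 0 and 2.

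The bins that the baits met more often than others at the same distance were then located within each genotype. Of the 41 bins tested for the TFAP2C bait, 17 lay at least 2-fold above the distance trend in both wild-type replicates and 15 in both p63-null replicates, and 7 were counted in both genotypes. On the higher side lay 15 and 12 of them, reaching 430 kb from the bait. Most of the 41 tested bins also lay on that side, and the loess took both sides together. The count on the higher side is therefore not a finding. The highest in wild-type were the bins starting at 55,595,001 (mean ratio 6.35), 55,560,001 (6.34), 55,420,001 (5.74), 55,550,001 (5.31) and 55,630,001 (5.25). In p63-null cells they were those at 55,580,001 (8.02), 55,425,001 (7.05), 55,550,001 (6.76), 55,560,001 (5.97) and 55,420,001 (5.86). The bin at 55,420,001, which is the 55.42 Mb bait, had 6 and 7 wild-type and 4 and 8 p63-null contacts. A pair of bait bins may have been amplified from the primers of either bait, unlike a bait with an ordinary bin. Ratios of bait bins, here and for the other baits below, may be raised by this, which was not tested. Bins were tested only if they held at least 10 contacts, which by itself favours bins above the trend, so the share of tested bins that lie above it is not a finding. Random sets of 17 and 15 out of 41 bins would share about as many as 7, so the overlap between genotypes is not a finding either. These ratios have no test, and a loess on each side apart counted 10 bins in wild-type.

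The 55.42 Mb bait had 6 such bins in wild-type and 9 in p63-null cells out of 59, and 2 were counted in both. Those 2 were the TFAP2C bait bin, with a mean ratio of 3.67 in wild-type and 5.15 in p63-null cells, and the next bin at 55,205,001, with 4.02 and 4.79. The remaining bins among the 5 highest began at 55,545,001 (5.29), 55,630,001 (4.83) and 55,695,001 (4.46) in wild-type, and at 55,570,001 (6.50), 55,635,001 (3.83) and 55,250,001 (3.70) in p63-null cells. With a ratio of 1.5 the wild-type count was 16. The 55.38 Mb bait had 3 bins above the trend in wild-type, at 55,200,001 (5.64), 55,505,001 (3.23) and 55,535,001 (3.16), and 1 in p63-null cells, at 55,420,001 (5.92). With a ratio of 1.5 these counts were 7 and 2.

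**Figure D2:**
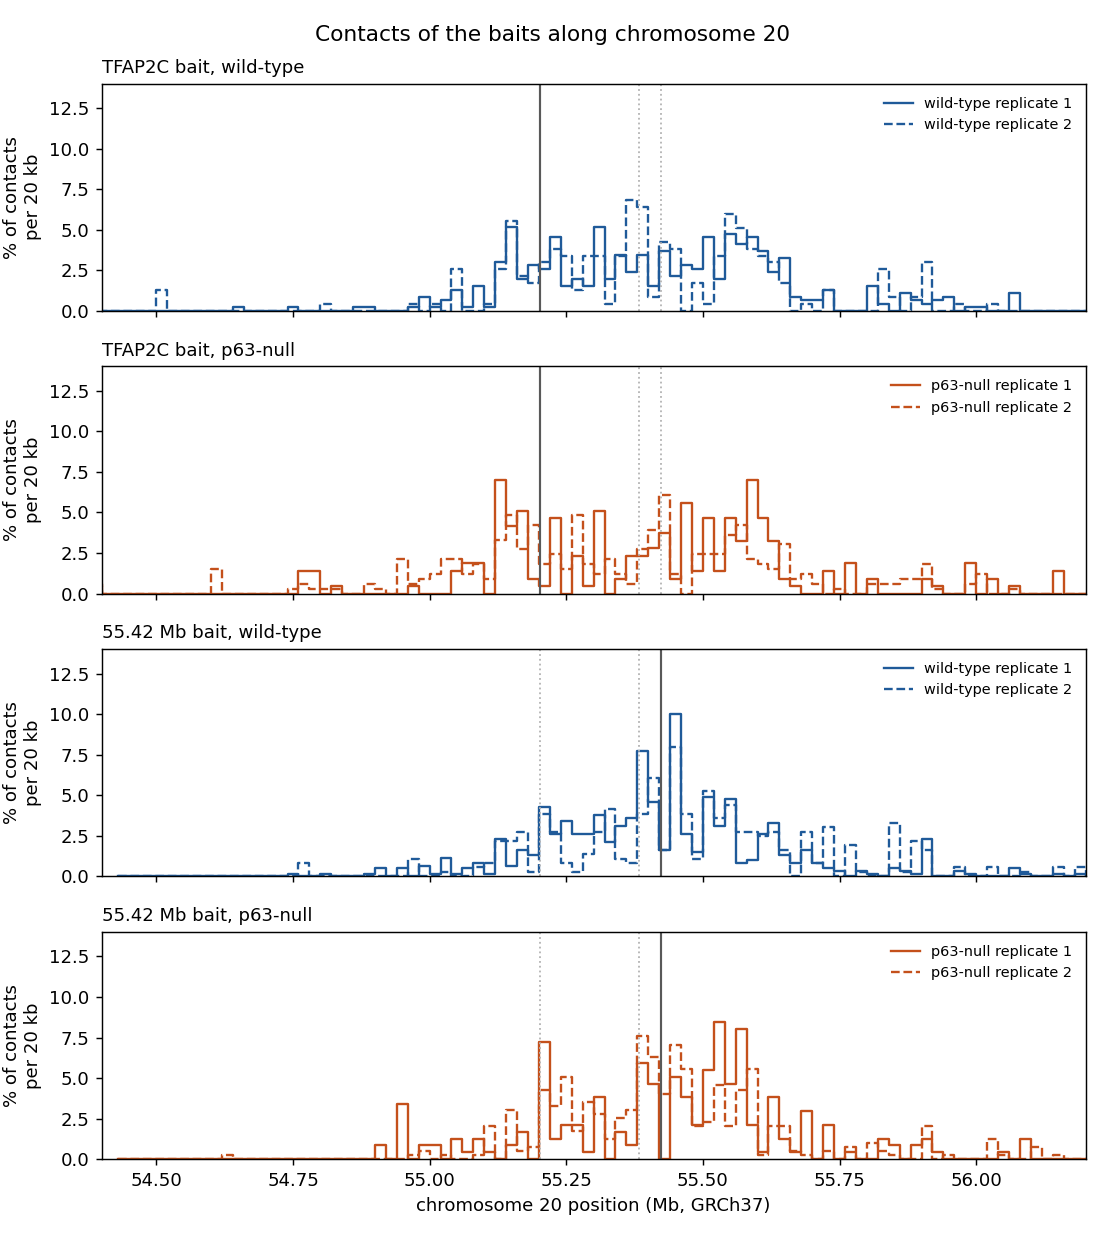
Contacts of the TFAP2C bait and of the 55.42 Mb bait per 20 kb, as a percent of the contacts of that bait within 1 Mb (vertical axis), along chromosome 20 in Mb (horizontal axis). Lines are single libraries, solid for replicate 1 and dashed for replicate 2, the solid vertical line marks the bait and dotted lines the other baits. The highest 20 kb of the TFAP2C bait held 5.17 and 6.81% in the wild-type and 6.98 and 6.06% in the p63-null libraries. These highest places differed between libraries. At 55.36 Mb, the highest of wild-type replicate 2, the wild-type libraries held 2.37 and 6.81% and the p63-null libraries 2.33 and 0.61%.

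Contacts between the baits were compared in windows of 15 kb, chosen after the data were seen. The TFAP2C bait met the window around the 55.38 Mb bait 14 and 12 times in wild-type and 0 and 2 times in p63-null cells. The pooled ratio was 0.099 (exact interval 0.011 to 0.394, counting error only). This window did not pass, with a log2 fold change of -3.35 (SE 1.39) and an edgeR adjusted p of 0.710 over the 38 windows tiled from it. Adjusted over the 6 windows around other baits alone, p was 0.112. The log2 fold change was -2.61 without p63-null replicate 1, and without p63-null replicate 2 no p63-null contact was left to give a fold. Read from the 55.38 Mb bait, the window around the TFAP2C bait had 5 and 9 against 3 and 3 contacts and a log2 fold change of -0.62, which turned to 0.28 without wild-type replicate 2 and was -1.31 without wild-type replicate 1. Of these contacts 3 and 8 against 0 and 2 were the pair of bait bins itself, which is counted in both readings. The TFAP2C bait met the window around the 55.42 Mb bait 9 and 10 times in wild-type and 9 and 24 times in p63-null cells, a log2 fold change of 0.96 with an edgeR adjusted p of 0.672 over 41 tiled windows. It was 0.44 without wild-type replicate 1, 0.51 without p63-null replicate 2 and 1.56 without wild-type replicate 2. From the 55.42 Mb bait, the window around the TFAP2C bait had 17 and 14 against 7 and 20 contacts and a log2 fold change of 0.32, which turned to -0.14 without p63-null replicate 2 and was 0.62 without p63-null replicate 1.

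Replicates of a genotype differed by more than sampling noise, except the p63-null replicates of the 55.38 Mb bait. For the TFAP2C bait the chi-square per degree of freedom was 2.74 between the wild-type and 4.13 between the p63-null replicates, over 17 and 8 bins. For the 55.42 Mb bait it was 2.32 and 4.13, over 29 and 19 bins. For the 55.38 Mb bait it was 5.43 over 3 bins in wild-type (chi-square p 0.000985). In p63-null cells it was 1.61 over 1 bin, where no difference was detectable (chi-square p 0.205). Across 20 kb bins, which are not independent replicates, Pearson's r between replicates was 0.789 and 0.593 for the TFAP2C bait, and 0.818 and 0.730 for the 55.42 Mb bait, wild-type before p63-null. For the 55.38 Mb bait it was 0.749 and 0.438. Across the 5 kb bins r was lower, at 0.474 and 0.331 for the TFAP2C bait and 0.599 and 0.346 for the 55.42 Mb bait. The 55.38 Mb bait had 0.443 and 0.280 there. Each library was kept as a replicate as labelled, and this excess does not show that they came from separate cultures.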

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

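The signals in this paragraph came from contacts beyond 1 Mb of a bait or within single bins, which the comparisons leave out, and for the 3 patterns that follow, the tests of random ligation, of depth and of the 55.38 Mb window were chosen only after the result was seen. The requirement that a gap exceed the replicate difference was also added then. The TFAP2C bait met the bin at 61,470,001 to 61,475,000, 6.27 Mb away, 277 times over the 4 libraries, between 61 and 83 times in each. The bins within 50 kb of it held 16 contacts, 5.78% of that number, against 1.28 expected from the density beyond 1 Mb. Bounds of under 5% and of at least 20% had been set for this share beforehand, and neither was met. The 55.38 Mb bait met the bin at 37,575,001 to 37,580,000 108 times, between 19 and 37 times in each library. Among bins that are not baits, those at 24,460,001 and 55,960,001 held a mean of 74 and 120.5 contacts within the bin over the 4 libraries, where the median of bins with any was 1 to 2.

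The TFAP2C bait met its lower side more often in both p63-null libraries than in both wild-type libraries. Random ligation falls short of it: the density beyond 1 Mb would give 7.20% of the p63-null contacts counted between 100 kb and 1 Mb on that side. A few products counted many times stay open: with each bin counted once, the lowest p63-null share exceeded the highest wild-type share by 1.2 percentage points, against 11.5 between replicates. Depth stays open too. The libraries nearest in bait contacts, wild-type replicate 2 and p63-null replicate 1, differed by 5.36 points in the lower share beyond 100 kb, against 12.7 between replicates. By all contacts on chromosome 20, wild-type replicate 1 and p63-null replicate 1 were nearest, with lower shares of 8.19 and 12.4%. A change with loss of p63 may also account for it and remains untested beyond the band test, whose adjusted p over all 30 bands looked at was 0.123.

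Counts of single bins differed between replicates by more than Poisson noise. If the same ligation products were counted repeatedly, bins beyond 1 Mb would hold several contacts each. Leaving out bins of 10 or more contacts, they held a mean of 1.48 per bin contacted over the 3 baits, above the 1.01 of a Poisson model but short of the bound of 1.5 set beforehand; over the 2 planned baits alone it was 1.55, so the choice of baits decides the side of that bound. Distant bins that truly recur would be met in other libraries more often, and bins with 2 or more contacts were met elsewhere 1.27 times as often as bins with 1 (interval 1.02 to 1.58, or up to 1.67 with the 2 most frequent bins included), short of the 3 times set beforehand for recurrence as the cause, though the interval reaches past the 1.5 set for its absence. Some recurrence and repeated counting stay open, and no biological explanation was tested.

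The TFAP2C bait met the 15 kb around the 55.38 Mb bait less often in both p63-null libraries, without passing the test. With a few ligation products counted many times in mind, each of the 9 bins within 20 kb was counted once: 7 and 6 were met in wild-type and 4 and 6 in p63-null cells, a gap of 0 bins between the genotypes. For a background difference of the TFAP2C bait library, the 55.38 Mb bait was read in the other direction, over the 9 bins around the TFAP2C bait. There the lowest wild-type share minus the highest p63-null share was -0.31 percentage points, against 4.98 between replicates. That reading partly reuses the observation, since the pair of bait bins is the same count either way, and without the pair the value was -1.22 on 4 to 7 contacts per library. Both explanations may hold, and so may an effect of p63, since these counts are too few to decide.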

How the results depend on the processing

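The 55.38 Mb bait, the 15 kb windows, the distinct partner bins and the crossed block were chosen after the data were seen. The count of bins past the threshold was 0 under every alternative run for all 3 baits, except without p63-null replicate 1, where it was 1 for the 55.42 Mb bait. The 1 band called for the TFAP2C bait became 0 with TMM, DESeq2, the replicate block, scaling to all of chromosome 20, the crossed block and distinct partner bins, and that band did not pass when any 1 library was left out. The count was 0 to 1 with a library left out, the 1 being another band (lower 100 to 250 kb, without p63-null replicate 1). The log2 fold change of the band at 250 to 500 kb stayed between 1.5 and 2.82, with adjusted p from 0.0602 to 0.476. Leaving out a library also leaves a lone sample assumed to vary like the other genotype. The replicate block, besides ending that call, gave 1 band for the 55.38 Mb bait and changed no other count of bins or bands. The labels' replicate numbers are not shown to pair libraries: same-numbered deviations correlated at 0.018, -0.13 and 0.14 for the 3 baits, and the crossed block called 0 bins and 0 bands. Wild-type bins above the trend went from 17 to 10 with a loess on each side apart (TFAP2C bait), and with a ratio of 1.5 from 6 to 16 (55.42 Mb bait) and from 3 to 7 (55.38 Mb bait), where p63-null went from 1 to 2.

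Differences in share (p63-null minus wild-type, percentage points) turned sign with all of chromosome 20 as denominator to -0.28 (TFAP2C bait, higher 500 to 1000 kb), -0.49 and -0.42 (55.42 Mb bait, lower 10 to 50 and 100 to 250 kb). With a library left out, those of the TFAP2C bait ran from -0.16 to 1.38 (lower 50 to 100 kb), -0.39 to 2.18 (lower 500 to 1000), -2.24 to 1.94 (higher 50 to 100), -6.83 to 4.32 (higher 250 to 500) and -0.42 to 1.03 (higher 500 to 1000). Those of the 55.42 Mb bait ran from -1.84 to 3.05 (lower 10 to 50), -2.14 to 4.73 (lower 100 to 250), -1.09 to 3.36 (lower 250 to 500), -7.85 to 3.06 (higher 10 to 50), -1.34 to 4.64 (higher 50 to 100) and -8.52 to 0.52 (higher 250 to 500). Window log2 fold changes ran from -3.69 to -2.61 and 0.44 to 1.56 (TFAP2C bait with the 55.38 and 55.42 Mb windows, the former leaving out the fit without p63-null replicate 2, whose p63-null arm had 0 contacts), -0.14 to 0.62 and -0.42 to 1.54 (55.42 Mb bait with the TFAP2C and 55.38 Mb windows), and -1.31 to 0.28 and -0.40 to 1.06 (55.38 Mb bait with the TFAP2C and 55.42 Mb windows). The cause was not tested. The lower-side share of the TFAP2C bait differed by 8.20 to 15.6 points with a library left out. Both p63-null libraries lay above both wild-type libraries, so leaving out a library could not turn this sign and is no test of it. With all of chromosome 20 as denominator, the difference was 5.28 points. The promoter alternatives were not run. At 215 to 464 contacts per library of the TFAP2C bait, 7.5% of simulated 8-fold changes of 5 kb bins were called, against 100% of bands. The share for bands rests on a single mean dispersion and may be too high.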

Other observations

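An interval of 600 kb, chosen after the data were seen, held most contacts of all 3 baits between 10 kb and 1 Mb. Contacts beyond 1 Mb are outside these shares. They made up 37.7 to 49.9% of the TFAP2C bait contacts per library. For the 55.42 Mb bait they were 21.4 to 30.2%, and for the 55.38 Mb bait 39.6 to 49.3%. Between 55,100,001 and 55,700,000 lay 85.2% ± 0.44 of the TFAP2C bait contacts within 1 Mb in wild-type and 76.9% ± 5.04 in p63-null cells (SD, n = 2 each). The interval was set from 100 kb below to 500 kb above the TFAP2C bait. Its share for that bait therefore mostly restates the lower-side difference given in the Results and is no separate evidence. For the 55.42 Mb bait these shares were 82.8% ± 5.30 and 86.0% ± 5.92, and for the 55.38 Mb bait 92.5% ± 2.65 and 79.4% ± 0.79. For the TFAP2C and 55.38 Mb baits both p63-null libraries lay below both wild-type libraries, with an exact permutation p of 0.33, the smallest this design allows. The 55.42 Mb bait had p = 0.67 in the same exact permutation test. Contacts between bait bins themselves numbered 0 to 17 per pair and library. The 55.38 and 55.42 Mb bins met 17 and 3 times in the wild-type and 4 and 11 times in the p63-null libraries.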
